A study of Homo sapiens with 6 samples.

How the data were processed

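RNA from 6 samples of VP-16-treated A549 stable cells, 3 control and 3 labelled H2AX knockdown, was measured on Affymetrix arrays. The groups were taken from the sample titles and genotype labels. The cells had been starved of serum overnight and treated for 48 h, and biotinylated cRNA was made from 6 ug of total RNA, per the labels' protocols. The dose is written there as 100 with a unit that appears cut short, so no dose is used. The design text calls the samples of a group independent experiments, and does not say whether control and knockdown samples were handled in pairs. No untreated sample was analysed here, so the comparison is between the 2 groups under the drug and not of the drug's own effect.

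The values are the deposited log2 signals of 33297 probe sets per array, made with RMA per the submitters' processing notes, with the version not given in the sources used here. The scale was taken from the values, which ran from 0.611 to 13.2. As usually run, RMA subtracts background, normalizes between arrays and summarises the probes of a probe set, and it compresses differences of dim probe sets. The deposited arrays did not share one distribution: their SD ran from 1.60 to 1.86 and their medians from 3.38 to 3.53. Signal over background could not be read from these values, so no probe set was called absent. No column of values was left unused.

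Probe sets were named through a table of the platform's annotation, which can be old. Of the probe sets 19460 had 1 gene, 1754 had several and 12083 had no gene in that table, and the last 2 kinds were not named. Of those with 1 gene 19429 were matched by Entrez gene number to current names, which changed 0 symbols. For each of 18417 genes the probe set with the highest mean over the 6 arrays was kept, and 769 genes had more than 1. No filter on low signals was used. Genome positions were not used here.

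Genes were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the log2 values, knockdown-labelled minus control, with no covariate, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Values after ± are SDs over 3 arrays or standard errors, as marked. H2AX also had an exact permutation test of 3 against 3 arrays. Gene lists (23, with 684 of 748 entries measured) were fixed in advance and tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. Within each list p-values were also adjusted over the list alone. Each list's median was set against 10000 random lists drawn from the same of 50 bins of mean signal, as a description of these arrays, and this comparison was chosen after the shift with brightness was seen. Figures were drawn with matplotlib 3.10.9.

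The genes named were fixed by a rule: H2AX, up to 12 genes per direction past the threshold with no overlap between groups (all that passed were named), up to 4 members of each list past the threshold or, where a list passed and no member did, its 2 with the largest change, and the drug's targets. One gene of the rule and 1 of the 23 lists are not reported here, though the list is included in counts of lists and in the adjustment over lists. Genes named outside the rule are members called when adjusted over a list alone, and others chosen after their values were seen.

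The alternatives planned were the replicate number as a block, a filter at the median signal, quantile normalization, subtraction of array medians, the mean of all probe sets of a gene, every probe set tested, an intensity trend with robust variance, array weights, and each array left out in turn. Cyclic loess with 5 iterations was chosen after seeing the data. The procedure was tested on simulated arrays for the comparison of 3 against 3, with 18417 genes. It recovered 60% of the 100 genes changed by 1 on the log2 scale and 98% of the 100 changed by 2, all with the right sign, with 4 false among 162 calls. A list shifted by −0.4 was recovered, and 0 of the 22 other lists were called. The simulated noise was independent between genes and had no shift with brightness. The simulation therefore does not show how the list test behaves on correlated genes.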

Results

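The series measured gene expression in A549, a human lung adenocarcinoma cell line, with Affymetrix arrays. All 6 samples had been treated for 48 h with VP-16, which is etoposide, a drug that traps topoisomerase II on broken DNA and so causes double-strand breaks. Control stable cells (3 arrays) were compared with stable cells labelled as having a knockdown of H2AX (3 arrays), the histone variant that is phosphorylated around double-strand breaks. The comparison asks which genes differ in expression between control cells and cells carrying this knockdown label when both are treated with the drug. Apoptosis itself was not measured in these data. Each array gave a log2 signal for 33297 probe sets, and 18417 genes were tested. The number of arrays limits the precision. The number of stable lines behind each group was not used here. If each group came from a single line, the tests measure the spread between experiments and not between lines.

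The signal of H2AX itself was not lower in the arrays labelled H2AX knockdown. The log2 signal of its probe set (probe set 7952179, Entrez gene 3014) was 5.21 ± 0.09 in the control arrays (SD, n = 3) and 5.31 ± 0.16 in the knockdown-labelled arrays (SD, n = 3). The difference, knockdown-labelled minus control, was 0.10 with a 95% interval of −0.25 to 0.45 (limma adjusted p = 0.823; exact permutation test, 2-sided, p = 0.4, where the smallest p that 3 against 3 arrays allow is 0.1). The lower bound excludes a fall of more than 15.8% in the signal of this probe set. H2AX had 1 probe set with a single gene, and its mean signal lay at the 83.9th percentile of genes. The signal of the targeted gene therefore does not show the labelled knockdown. Every direction below is that of the arrays labelled H2AX knockdown against control, not of a measured loss of H2AX.

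Few genes passed the threshold. In the knockdown-labelled arrays 5 genes were lower, among them the cytokine gene IL1B and the chemokine gene CXCL1, and 1 gene, SNORD41, was higher (limma, adjusted p under 0.05). All 6 differed by at least 2-fold with no overlap between the groups. SAA2, an acute-phase serum amyloid A protein (probe set 8180303), went from 4.96 ± 0.39 to 3.32 ± 0.19 (log2 signal, SD, n = 3 each) and fell by 1.65 on the log2 scale, with an adjusted p of 0.016. IL1B, the cytokine interleukin-1 beta (probe set 8054722), fell by 1.48, from 5.39 ± 0.26 to 3.92 ± 0.28, and CXCL1, a chemokine that attracts neutrophils (probe set 8095697), fell by 1.25, from 8.71 ± 0.15 to 7.46 ± 0.09. VAMP8, a SNARE protein of endosomal and lysosomal membrane fusion (probe set 8043197), fell by 1.32, from 6.18 ± 0.18 to 4.86 ± 0.08. These 3 genes had the same adjusted p of 0.016. FSTL1, a secreted glycoprotein (probe set 8089835), fell by 1.13, from 7.24 ± 0.22 to 6.10 ± 0.13 (limma adjusted p = 0.0464). SNORD41, a C/D box small nucleolar RNA of the class that guides RNA methylation (probe set 8034512), rose by 1.14, from 8.80 ± 0.22 to 9.95 ± 0.11 (limma adjusted p = 0.0442). SAA2 is nearly identical in sequence to SAA1, so the transcript behind its signal is uncertain: with all its probe sets averaged the difference was −0.85 (limma adjusted p = 0.137), and the probe set of SAA1 read 2.41 and 2.39.

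**Figure D1:**
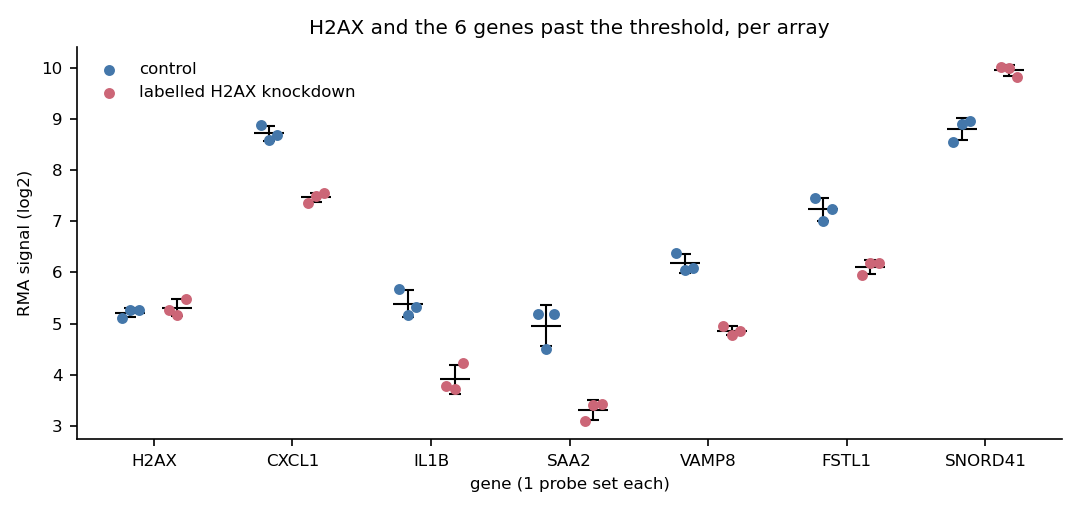
Log2 RMA signal of H2AX and of the 6 genes past the threshold in each array, as points, with the group mean and SD (bars, n = 3). The H2AX values of the 2 groups overlap, at 5.21 and 5.31 on average, while the groups do not overlap for the other genes.

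At an unadjusted p under 0.05, 696 genes were higher and 1544 lower in the knockdown-labelled arrays, where 921 would be called by chance. The groups did not overlap for 3128 genes, or 17% of those tested, against 10% by chance. These chance values are averages. Genes that move together, as in the shift with brightness below, can carry the counts of 1 comparison far from them. The count of 6 depended on the processing: array medians subtracted gave 4 lower and 0 higher, array weights gave 155 lower and 36 higher, and quantile normalization gave 0 genes in limma, with 1495 at an unadjusted p under 0.05. It was 0 without control replicate 1, control replicate 3, or knockdown-labelled replicate 1 or 2 (944, 1380, 1479 and 2296 genes at an unadjusted p under 0.05), 1 without control replicate 2, and 9 without knockdown-labelled replicate 3.

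Bright genes read lower, and dim genes higher, in the knockdown-labelled arrays. With genes placed in 5 bins by mean signal, the median log2 difference went from 0.15 in the dimmest bin over 0.07, −0.01 and −0.10 to −0.25 in the brightest, where 85.3% of genes were below 0. Against the mean of the controls, the median of the brightest bin was −0.45 in knockdown-labelled replicate 1, −0.15 in replicate 2 and −0.13 in replicate 3, and it was 0.14, −0.15 and 0.01 in control replicates 1, 2 and 3. Knockdown-labelled replicate 1 stood apart from the other arrays, with the smallest SD of all values (1.60, against 1.71 to 1.86) and a score of 42.6 on a principal component that held 49.2% of the variance. Control replicate 1 lay at the other end of that component, with a score of −31.7 and the largest SD (1.86). Each gene list below is therefore also set against 10000 random lists of the same size and brightness.

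**Figure D2:**
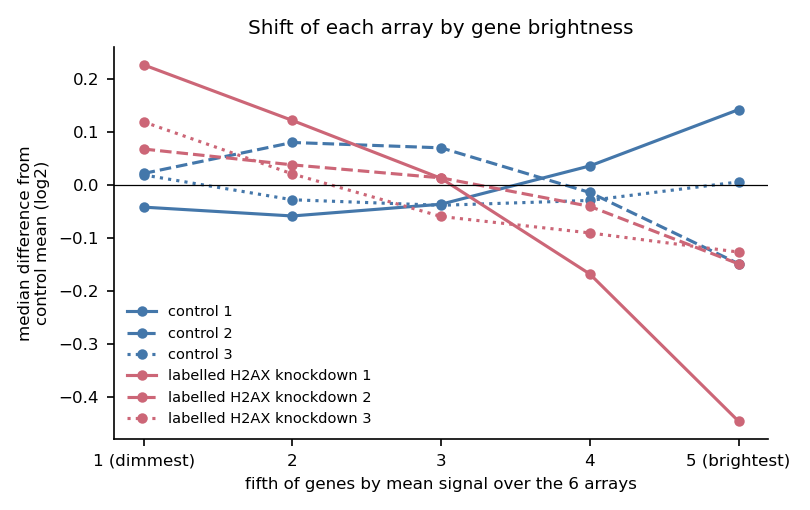
Median difference of each array from the mean of the control arrays (log2), for genes in 5 bins of mean signal from dimmest to brightest. The lines of the 3 arrays labelled H2AX knockdown run downwards, to −0.45 in replicate 1, −0.15 in replicate 2 and −0.13 in replicate 3. The line of control replicate 2 also ends at −0.15, while those of control replicates 1 and 3 end at 0.14 and 0.01, so the shift is not particular to the knockdown-labelled arrays.

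NF-kB targets and inflammatory cytokines had the lowest median of the lists fixed before the data were examined. Of its 36 measured genes 2 were lower past the threshold over all genes, IL1B and CXCL1, 34 were not past it, and 12 were lower when adjusted over the list alone. The log2 difference was below 0 for 30 of the 36, with a median of −0.40, or −0.26 after quantile normalization and −0.24 after cyclic loess, a setting chosen after seeing the data. The list test passed (camera with a preset correlation of 0.01, adjusted p = 5.4e-09), but not with an estimated correlation (adjusted p = 0.454) or in fry, which asks whether the genes of a list move one way (adjusted p = 0.0849). None of 10000 random lists of the same brightness had a median as low, and their central 95% ran from −0.26 to −0.07. Members named after their values were seen, all among the 12, were CCL20, a chemokine for dendritic and T cells (−1.45), VCAM1, an adhesion molecule (−1.21), CCL2, a monocyte chemokine (−1.13), and IL1A (−1.12), with a limma adjusted p over all genes of 0.0591 for VCAM1 and 0.074 for the others. IL6 had a value of −0.82, SOD2 of −0.81, CXCL2 of −0.80 and CXCL8 of −0.74. Other members did not show it: TNF was at −0.14, PTGS2 at −0.03 and ICAM1 at 0.27, none of them past the threshold. The control signal was 6.87 for PTGS2, but only 2.64 for TNF and 3.36 for ICAM1, and at such dim signals a fall is hard to read.

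Neither side of the apoptosis machinery held a gene past the threshold over all genes. The 12 measured anti-apoptotic genes were all below 0, with a median of −0.25 (−0.15 after quantile normalization), and 2 of them were lower when adjusted over the list alone: CFLAR, an inhibitor of caspase-8 activation (−0.71 ± 0.19, SE), and BCL2A1, a BCL2 family protein (−0.69 ± 0.197, SE). Of 31 pro-apoptotic genes 21 were below 0, with a median of −0.18 and 0 past the threshold either way, and 9 lower and 1 higher at an unadjusted p under 0.05. BAK1 (−0.72 ± 0.33, SE) and PMAIP1, which encodes NOXA (−0.62 ± 0.18, SE), had the largest values. BAK1 overlapped between the groups, with 3.20, 4.88 and 3.59 in knockdown-labelled replicates 1, 2 and 3, and 4.93, 4.36 and 4.55 in the controls. Both lists passed the test with a preset correlation (camera adjusted p = 0.000742 and 0.0165), and neither did with an estimated correlation (adjusted p = 0.517 for each). Random lists of the same brightness had medians as low in 13.4% and 16.9% of draws. The pro-apoptotic call was lost after quantile normalization (median −0.06, adjusted p = 0.49) and without knockdown-labelled replicate 3 (0.0615). After cyclic loess the anti-apoptotic call was lost as well.

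Genes of DNA double-strand break signalling and repair, the process in which H2AX acts, had a median of −0.14, with 26 of 36 below 0 and 0 past the threshold in limma (3 lower and 1 higher at an unadjusted p under 0.05). That median ran from −0.24 to −0.09 over the alternatives. The list passed barely (camera adjusted p = 0.0496), and not with an estimated correlation (adjusted p = 0.579). It was lost without control replicate 1 (0.234), control replicate 3 (0.0999), knockdown-labelled replicate 1 (0.0737) or knockdown-labelled replicate 2 (0.289). Random lists of the same brightness had a median as low in 0.15% of draws. TDP2, which releases topoisomerase II from DNA ends, had the largest value (−0.81 ± 0.207, SE, limma adjusted p = 0.248), followed by BAZ1B, a kinase of H2AX (−0.54 ± 0.166, SE, adjusted p = 0.289). Of the drug's own targets, TOP2A was at −0.06 (95% interval −0.46 to 0.34) and TOP2B at −0.47 (−0.87 to −0.08), with limma adjusted p of 0.914 and 0.357. The value of TOP2A was above 0 with array weights (0.02).

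Other histone and cell cycle genes did not pass the list test. The 17 measured H2A family genes had a median of −0.02 (camera adjusted p = 0.799) and the 32 other core and linker histone genes one of 0.08 (0.175). The latter passed without control replicate 3 (0.0202) and without knockdown-labelled replicate 1 (0.037), and its median lay above the central 95% of random lists, of which 0.85% were as high. Genes of DNA replication and S phase (44 measured, median 0.01) had an adjusted p of 0.911, and those of G2 and mitosis (45 measured, median 0.05) one of 0.771. Both medians turned below 0 after quantile normalization (−0.05 and −0.04). None of the genes in these lists was past the threshold over all genes or adjusted over its list alone. At an unadjusted p under 0.05 in limma, 2, 2, 5 and 3 genes of these lists were lower and 0, 2, 1 and 1 higher.

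Lists of bright housekeeping genes were lower in the knockdown-labelled arrays, as bright genes were in general. Mitochondrial respiratory chain genes (36 measured, 32 below 0) had a median of −0.33 and a camera adjusted p of 1.2e-06, with COX6A1 at −0.65 and ATP5F1C at −0.63. Cytosolic ribosomal proteins (35 measured, 31 below 0) had a median of −0.24 (adjusted p = 7.4e-06), with RPS13 at −0.68 and RPL10 at −0.66. With an estimated correlation the adjusted p was 0.517 and 0.579. After quantile normalization the medians were −0.16 and −0.09. Random lists of the same brightness were as low in 0.99% of draws for the respiratory chain and in 88.0% for the ribosomal proteins. No gene of either list was past the threshold, in limma, over all genes or adjusted over the list alone, with 14 and 11 lower at an unadjusted p under 0.05. Ribosomal protein genes have many processed pseudogenes, so single members are uncertain.

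Cholesterol synthesis and uptake genes (19 measured, 16 below 0) had a median of −0.24, or −0.13 after quantile normalization (camera adjusted p = 0.00478; adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone, 3 were lower: IDI1 (−0.75), INSIG1 (−0.59) and CYP51A1 (−0.51), an isomerase, a regulator and a demethylase of the pathway. DHCR7, a reductase of the pathway, was at −0.62, but its groups overlapped. It read 3.85, 5.07 and 5.09 in knockdown-labelled replicates 1, 2 and 3, and 5.37, 5.06 and 5.45 in the controls. Random lists of the same brightness were as low in 1.51% of draws.

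A further 5 lists that passed downwards lay within the central 95% of random lists of the same brightness. Autophagy and lysosome genes (33 measured) had a median of −0.24, and 3 were lower adjusted over the list alone: the lysosomal galactosidase GLA (−0.66), DRAM1 (−0.64) and GABARAPL2 (−0.62). Among NRF2 targets (30 measured, median −0.25) 1 was lower adjusted over the list alone, GCLC, an enzyme of glutathione synthesis (−0.77), and AKR1C2, which has near-identical paralogs, was at −0.66. Unfolded protein response and amino acid stress genes (35 measured) had a median of −0.25, with the chaperone DNAJB9 at −0.66 and MTHFD2 at −0.65. Hypoxia and glycolysis genes (31 measured) had a median of −0.24, with VEGFA at −0.69 and BNIP3 at −0.61. Immediate early and AP-1 genes (28 measured) had a median of −0.18, with JUN at −0.61 and IER3 at −0.47. In that order the camera adjusted p was 6.0e-05, 0.00014, 3.3e-05, 0.00118 and 0.0165, and the adjusted p with an estimated correlation was 0.562, 0.579, 0.517, 0.573 and 0.6. After quantile normalization none of these 5 passed (medians from −0.14 to −0.04, adjusted p from 0.0934 to 0.656), and the immediate early list also did not without control replicate 1 (0.134) or knockdown-labelled replicate 1 (0.346).

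Markers of other cell types and of cell identity gave 1 call. Fibroblast markers (15 measured, 13 above 0) were higher, with a median of 0.23 (camera adjusted p = 0.00365; adjusted p = 0.517 with an estimated correlation; 0.059 without knockdown-labelled replicate 1). The largest values were those of LUM, from 1.45 to 1.92, and DCN, from 1.79 to 2.26, both in the dimmest bin of genes, where the median of all genes was 0.15. The groups overlapped for both genes. DCN read 2.81, 1.83 and 2.12 in knockdown-labelled replicates 1, 2 and 3, and 1.85, 1.81 and 1.72 in the controls. Random lists of the same brightness were as high in 0.15% of draws. Blood and immune cell markers (19 measured, median 0.10) had an adjusted p of 0.669 and a median of −0.04 after quantile normalization. Epithelial junction and keratin genes (27 measured, median 0.03) had an adjusted p of 0.875, and the junction protein CLDN1 (−0.74) was lower adjusted over the list alone. Among mesenchymal genes (28 measured, median −0.07, adjusted p = 0.799, median 0.03 after quantile normalization), FN1, which encodes fibronectin, was higher adjusted over the list alone (0.56), and the transcription factor SNAI2 (−0.85) and the growth factor TGFB2 (−0.82) were lower. Lung alveolar and airway markers (23 measured, median 0.02, mean −0.05, adjusted p = 0.799) held 1 gene lower adjusted over the list alone, the caveolar protein CAV1 (−0.71). Type I interferon response genes (38 measured, median −0.06, adjusted p = 0.669) also held 1, PARP14 (−0.81).

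**Figure D3:**
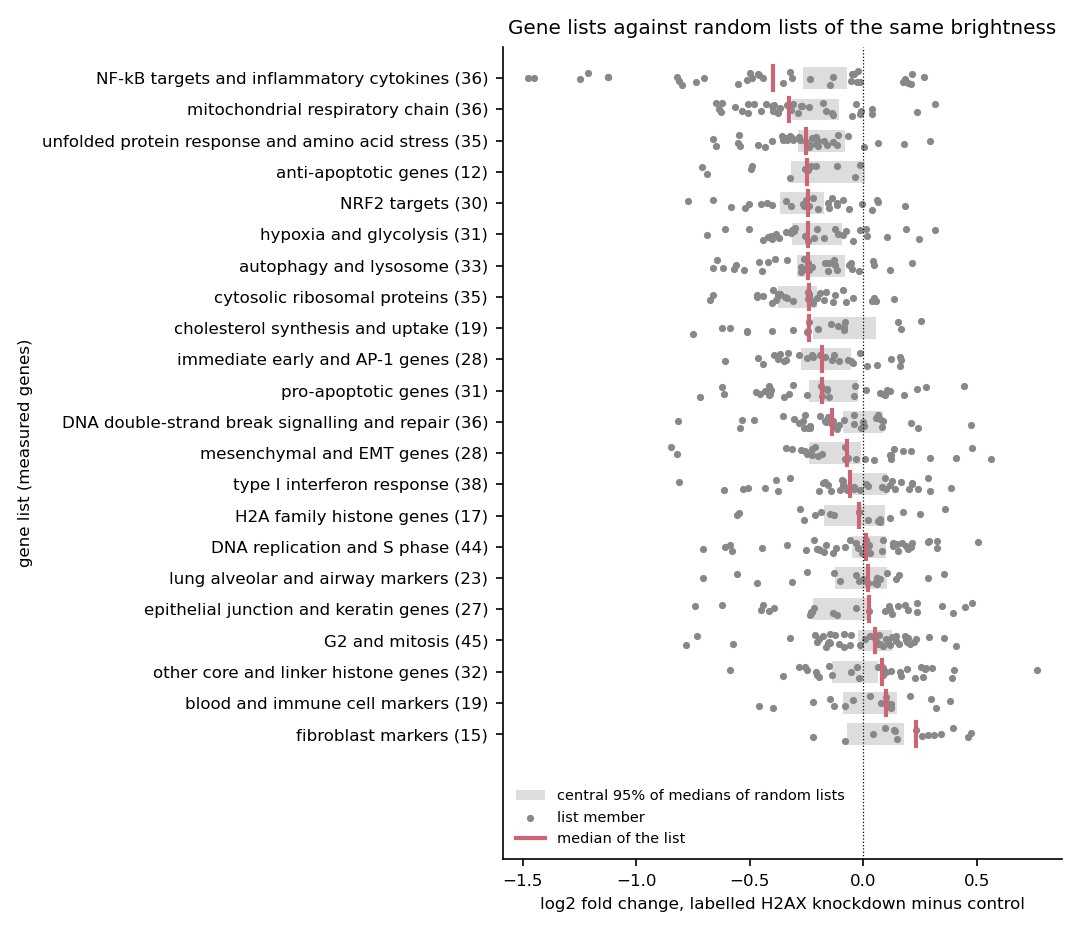
Log2 difference (knockdown-labelled minus control) of each measured gene of 22 lists, as points, with the median of each list (line) and the central 95% of medians of 10000 random lists of the same size and brightness (grey band). Medians of 4 plotted lists lay below their band, with NF-kB targets and inflammatory cytokines lowest at −0.40, and 3 lay above it.

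Of the 23 lists, 13 passed downwards and 1 upwards with the preset correlation, and 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) or in fry (4 at an unadjusted p under 0.05). The medians of 8 of the 13 lists lay inside the central 95% of random lists of the same brightness.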

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

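Cyclic loess was chosen after seeing the data, and all the other alternatives before. The alternative that leaves out probe sets marked for cross-hybridisation was not run, because the numeric IDs carry no such marks. In all 14 alternatives H2AX was not lower past the threshold, with a difference of 0.01 to 0.26 (adjusted p 0.664 to 0.987), and the 6 called genes kept their sign in each one. Their adjusted p was 0.0578 to 0.0971 after quantile normalization and 0.0657 to 0.0901 after cyclic loess, where the differences of FSTL1 shrank to −0.89 and −0.87. Over all alternatives IL1B stayed at −1.33 or lower, VAMP8 at −1.11 or lower, CXCL1 at −1.01 or lower and SNORD41 at 1.02 or higher. The difference of SAA2 shrank to −0.85 at the least. Of alternatives for the gene lists, 275 kept direction and side of the threshold, 61 lost the call, 2 gained it and 30 turned direction. For single genes these were 411, 51, 7 and 3. Only a list that had passed, or 1 of the 6 called genes among the 34 followed, had a call to lose. All 51 losses thus fell on those 6 genes. Most of the 411 are genes that were not called and stayed so, so these counts do not show that the calls were stable. Signal over background is not known from these values, so dim genes carry an unknown share of background.

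No pairing by replicate number was seen, but whether samples were handled in pairs stays open. Deviations from the group means correlated at −0.31, −0.02 and 0.07 across genes for equal numbers. Not every sample correlated best with its own number (0.37 for control replicate 1 with knockdown-labelled replicate 3). Deviations within a group cancel, which forces mixed signs, and they carry the shift with brightness, so this check cannot settle pairing. With the replicate block 3 genes were lower and 0 higher (1830 at an unadjusted p under 0.05), 3 and 0 of them at least 2-fold, and 14 lists passed.

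Counts of genes, lower and higher, moved with most settings. They were 3 and 0 with the mean of probe sets (3 and 0 at least 2-fold), 4 and 0 with array medians subtracted (0 at least 2-fold higher), and 155 and 36 with array weights (17 and 3 at least 2-fold), where control replicate 3 had a weight of 5.03. Without genes below the median level they were 14 and 2 (12 lower at least 2-fold), with all 6 called genes among them; fewer genes were then tested, and the median of all genes was −0.14. Quantile normalization and cyclic loess gave 0 in each direction and size (1495 and 1506 at an unadjusted p under 0.05 in limma), and so did every probe set tested (3611 probe sets). With 1 array left out, lower genes ran from 0 to 8 and higher genes from 0 to 1, and so did those at least 2-fold.

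List tests that passed were 7 after quantile normalization, 6 after cyclic loess, 6 without dim genes, and 0 with an estimated correlation or in fry. With an estimated correlation the adjusted p was 0.454 for NF-kB targets, 0.517 for pro-apoptotic and anti-apoptotic genes, and 0.579 for double-strand break repair. In fry it was 0.0849 for NF-kB targets, 0.227 for both apoptosis lists and 0.261 for repair. The NF-kB list passed after quantile normalization (5.7e-06, median −0.26) and cyclic loess (1.3e-05, median −0.24). Pro-apoptotic genes lost the call after quantile normalization (0.49), cyclic loess (0.548) and without dim genes (0.199), and ran from 0.0054 to 0.0615 with 1 array left out. Anti-apoptotic genes lost it after cyclic loess (0.0546). Repair genes lost it without dim genes (0.155) and with the mean of probe sets (0.0676), and ran from 0.00969 to 0.289 with 1 array left out.

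Directions that turned were those of TOP2A and of lists that never passed, given here as adjusted p. TOP2A was at 0.022 with array weights, and from −0.171 to 0.081 with 1 array left out. DNA replication turned with array weights (0.756), cyclic loess (0.465), quantile normalization (0.49), without dim genes (0.814) and in fry (0.621), and ran from 0.697 to 0.977 with 1 array left out. G2 and mitosis turned with cyclic loess (0.465), quantile normalization (0.49) and in fry (0.924), and ran from 0.332 to 0.937. Mesenchymal genes turned with cyclic loess (0.256), quantile normalization (0.308) and without dim genes (0.941), and ran from 0.409 to 0.971. Immune markers turned with cyclic loess (0.937) and quantile normalization (0.942), and ran from 0.144 to 0.973. Lung markers turned with array weights (0.94) and without dim genes (0.203), and ran from 0.211 to 0.977. Epithelial genes turned without dim genes (0.623) and in fry (0.80), and ran from 0.567 to 0.977. H2A family genes turned only with 1 array left out (0.544 to 0.971). Where the construction of a setting does not show it, the cause was not tested.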

Other observations

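The gene lists and tests of this part were chosen only after the results were seen, except those of other splits for the counts of genes and lists. For the tests of brightness, clustered copies and non-coding hosts, the criterion was set before its own value was computed, but after the shift with brightness was seen. The lists of this part were assembled after gene values had been seen, so their tests describe these arrays and are not independent evidence. Of 115 C/D box small nucleolar RNAs 107 were above 0 in knockdown-labelled minus control, with a median of 0.29, 1 past the threshold over all genes (SNORD41) and 16 higher adjusted over the list alone. Examples are SNORD57, from 10.1 to 10.9 (0.78), SNORD114-3, from 6.62 to 7.44 (0.81), and SNORD45B, from 3.94 to 4.88 (0.93). Of 61 H/ACA box RNAs, which guide pseudouridylation, 49 were above 0, with a median of 0.16. The camera adjusted p was 6.5e-19 and 7.7e-07, and 0.11 for each with an estimated correlation.

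Of 36 proteasome subunit genes 32 were below 0, with a median of −0.43 (−0.21 after quantile normalization and −0.19 after cyclic loess) and 11 lower adjusted over the list alone, 1 higher (camera adjusted p = 3.3e-10; 0.11 with an estimated correlation). PSMB5, a catalytic subunit, was at −0.80, PSMA3 at −0.78 and PSMA1 at −0.78. Of 23 heat shock proteins and chaperones 22 were below 0, with a median of −0.44, or −0.25 and −0.24 after these normalizations (camera adjusted p = 2.1e-09; 0.11 with an estimated correlation), and CHORDC1, which was put in the list after its value of −1.19 had been seen, had a limma adjusted p of 0.0591 over all genes. Secreted proteins of liver type (25 measured) had a median of 0.08, or −0.01 after quantile normalization, with a camera adjusted p of 0.0281 (0.147 after quantile normalization; 0.11 with an estimated correlation). Random lists of the same brightness had a median as high in 18.9% of draws, with a central 95% of −0.06 to 0.14. Its members went both ways: adjusted over the list alone 1 was higher, FGB, the fibrinogen beta chain (0.92, limma adjusted p over all genes = 0.0974), and 1 lower, CP, or ceruloplasmin, the copper protein of plasma (−0.82, limma adjusted p over all genes = 0.209), while FGG, the fibrinogen gamma chain, was at −0.23 (limma adjusted p over all genes = 0.7). RAD51C, a homologous recombination gene outside the fixed lists, was at −0.93 (limma adjusted p = 0.0773).

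The H2AX signal was not lower in the arrays labelled knockdown. An exchange of the labels of the 2 groups, with a knockdown of at least 2-fold, would give a log2 difference of 1. The upper bound of the 95% interval, 0.447, lies below that. This argues against such an exchange only if the probe set follows the H2AX transcript, which is not known. An exchange of single arrays was not tested. Whether a fall can show at this brightness was weighed on other probe sets only: 1 gene, VAMP8, among 2942 within 0.5 of the mean log2 signal of H2AX fell by at least 1 past the threshold, and SAA2 and IL1B fell by 1.65 and 1.48 from control signals of 4.96 and 5.39, against 5.21 for H2AX. Falls from such a signal did show on these probe sets. They were picked as ones that had passed, so they cannot show whether a fall would read on the H2AX probe set. The background of the H2AX probe set and signal of other transcripts on it stay open too, since H2AX has 1 probe set. Also untested are a knockdown lost during culture or under the drug, and one that acts on the protein more than on the transcript.

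NF-kB targets and inflammatory cytokines were lower in the knockdown-labelled arrays. Brightness-dependent compression as the whole cause is argued against by 0% of 10000 random lists of the same brightness with a median as low, and knockdown replicate 1 alone by the list test without that array (adjusted p = 3.7e-08, within 4.4e-10 to 0.454 over all alternatives). Of the 10 splits of the 6 arrays 1, the real one, gave a camera p as small (2.4e-10). The others gave a camera p of 0.000821, 0.00112, 0.00184, 0.00924, 0.0173, 0.0225, 0.138, 0.288 and 0.857. A camera p under 0.05 was thus not particular to the real split, and 10 splits are too few for a share under 0.05. Whether the difference comes from H2AX, whose probe set did not read lower, or from another difference between the stable cells was not tested.

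C/D box small nucleolar RNAs were higher in the knockdown-labelled arrays. Of 10000 random lists of the same brightness 0% had a median as high. Without the SNORD113 to SNORD116 copies 69 RNAs were left, with a median of 0.27 (random lists −0.11 to 0.04), and the share was again 0%. The class was chosen after gene values had been seen, so these shares cannot decide on brightness-dependent compression. For near-identical clustered copies, they show only that the other RNAs of the class read higher as well. Only 3 non-coding hosts were measured (median −0.12, range −0.33 to −0.09), too few to weigh whether higher host transcripts explain the rise. For 25 RNAs in introns of 15 protein-coding hosts, the host transcripts did not read higher as a set. These hosts had a median of −0.24 (95% bootstrap interval −0.40 to −0.13, with an upper bound of 0.02 after cyclic loess) against 0.35 for the 25 RNAs. The host median was close to that of the brightest bin of all genes (−0.25). It was −0.14 after quantile normalization and −0.13 after cyclic loess. Transcription of the hosts was not measured, and the RNAs belong to a class chosen after values were seen. Whether the hosts explain the rise therefore stays open. Of the 10 splits 2 gave a camera p as small, with 9.0e-30 for control replicates 1 and 2 with knockdown-labelled replicate 1 against the rest and 1.3e-19 for the real split. The C/D box RNAs therefore also follow a structure of the samples other than the groups. A difference in the recovery of small RNAs between extractions could give such a structure, and was not tested.

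For the counts of genes, 1 of the 10 splits gave as many higher genes (1, highest of the others 0), 1 as many lower genes (5, highest of the others 0), 1 as many at least 2-fold higher (1 and 0) and 1 as many at least 2-fold lower (5 and 0), the real split in each case. For gene lists past the threshold, 2 of the 10 splits gave as many (14 in the real split and 14 with control replicates 1 and 3 and knockdown-labelled replicate 3 against the rest). The remaining splits gave from 0 to 13 lists. With 10 splits no share can be under 0.05.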
